A study of Mus musculus with 12 samples.

How the data were processed

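Long RNA and miRNA were sequenced from RAW 264.7 cells infected with Staphylococcus aureus, with or without erastin at 20 µM for 6 h, in 12 libraries. Per the labels, the groups were infected cells and infected cells with erastin, each with replicates 1 to 3 in each RNA class. The labels also carry a blood source and a tumour cell type, RNA extraction with RNAiso Plus, and a stranded mRNA kit that is stated for the miRNA samples too. The submitters' processing notes name fastp, HISAT2, StringTie and the mouse build GRCm39, without versions, roles or order. Annotation release, filters and the way reads were matched to miRNAs are not given in the sources used here. The long RNA table deposited by the authors holds TPM, a length-scaled transcript share, for 57010 Ensembl gene IDs, scaled by the authors to the same total in each library. The miRNA table deposited by the authors holds RPM (reads scaled by the authors to a fixed total of miRNA reads per library, called TPM by them) for 1333 mature miRNAs. In all, 12 columns of per-sample values matched no sample of the series and were not used.

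Gene symbols came from the gene name table of the reference set, which matched 52029 of 57010 IDs, and 256 tested IDs had no symbol. No genome of the build used was at hand, so positions, GC content and gene lengths were not analysed here. How reads shared by near-identical copies were divided is not given in the sources used here, so Ifit3 (with Ifit3b), Fth1 and Ldha (with pseudogenes), histone genes and miRNAs of like sequence are uncertain. Replicates were compared before use. Counts of reads in pairs of miRNA replicates differed by 5.13 to 15.2 times the sampling variance (chi-square per degree of freedom), and long RNA replicates had 0.577% to 0.723% identical values among tested genes, so no library was a copy of another.

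TPM values keep no depth, so the precision of the long RNA values rests on replicates alone. Every RPM value was a whole multiple of 1 step per library, with 100% of values whole within 0.1 read, which gave back 6253372 to 6922903 reads per library. Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided, 3 against 3 libraries). Adjustment was by Benjamini-Hochberg with a threshold of 0.05. The filter was a mean over the 6 libraries of at least 1 TPM for genes, leaving 11616, and at least 10 RPM for miRNAs, leaving 265. Changes on this scale understate those of low genes. Files were normalized separately and each was tested within itself.

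Before the data were examined, 42 gene lists and 6 miRNA lists were fixed, on stress, redox, iron, immune, metabolic and growth genes and on markers of other cells. Lists with at least 3 tested members were tested with camera, which asks whether the members rank higher or lower than other genes, with a preset correlation of 0.01. The markers of 6 other cell types had fewer members tested, and their levels were given instead. Camera with an estimated correlation and fry were alternatives, and members were also adjusted over the list alone. Genes to name were fixed in advance. The rule took, among genes past the threshold with separated groups, a mean of at least 5 TPM and an ordinary symbol, the 10 largest rises and 10 largest falls, or the 5 smallest p in each direction if none passed. It added the 3 members with the smallest p of each list past its threshold and of the first 5 lists, and 13 genes whatever their result. These were Slc7a11, Chac1, Gpx4, Hmox1, Ptgs2, Tfrc, Fth1, Acsl4, Nos2, Il1b, Il6, Tnf and Pycard. For miRNAs it took 6 rises and 6 falls at a mean of at least 10 RPM, with miR-155-5p, miR-146a-5p, miR-21a-5p and miR-223-3p. Other members that passed when adjusted over a list alone, and the markers of macrophages and other cells, were named after their values were seen.

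Replicate numbers are shared between the groups in the labels. In the miRNA table the deviations of same-numbered libraries from their group means correlated at 0.174, 0.142 and 0.122, all over 0.1. These numbers were therefore taken to pair the miRNA samples, a pairing that comes from the values and not from the labels. With 3 libraries per group this is weak evidence. Same-numbered long RNA libraries correlated at 0.109, -0.182 and 0.091 and were not taken as pairs. The main test stayed unpaired, with the pairing as a block among the alternatives. Alternatives fixed in advance were other pseudocounts and filters, median-of-ratios and quantile scaling, rescaling without the most abundant features, no trend, the replicate block, a minimum change, leaving out each library, and for miRNAs edgeR 4.0.16 (quasi-likelihood test) on the recovered reads, which called 23 miRNAs, 7 higher and 16 lower. DESeq2 1.42.0 on those reads, edgeR with the block, library weights, a robust prior and an estimated correlation without control replicate 1 were added after seeing the data.

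The limma step was tested on simulated data with 11616 genes, a seeded set of which was changed. It recovered 14.9% of genes changed by 0.5 on the log2 scale, 92.5% of those changed by 1 and 100% of those changed by 2, and called 9 of 11416 unchanged genes. With 265 simulated miRNAs, limma and edgeR each recovered 100% of those changed by 0.5, 1 or 2, and called 3 and 1 of 225 unchanged miRNAs. The limma simulations used independent noise with a spread smoothed over expression, and no library stood apart as control replicate 1 does here. These shares therefore do not give the power in the real long RNA set. There Hmox1 changed by 2.06 and did not pass limma (adjusted p = 0.0618). Smaller changes, such as most of the miRNA calls here, were not simulated.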

Results

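RAW 264.7 cells, a mouse macrophage line, were infected with Staphylococcus aureus, a bacterium that can live inside macrophages. Erastin was added to part of the infected cells at 20 µM for 6 h. Erastin is a small molecule that blocks system xc-, the cystine importer built around Slc7a11, and it is widely used to start ferroptosis, an iron-dependent cell death with lipid peroxidation. RNA was sequenced in 12 libraries. The long RNA set held 3 infected libraries without erastin, called control here, and 3 with erastin, and the miRNA set held the same numbers. No uninfected cells were part of the series, so the effect of infection itself was not measured. The depth of the long RNA libraries is unknown, since TPM values keep no read totals. The miRNA libraries held 6253372, 6922903 and 6916599 miRNA reads in the control group, and 6813193, 6889673 and 6265081 with erastin. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

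The first comparison asked which host genes differed between infected macrophages with and without erastin. Genes of the amino acid and integrated stress response were higher with erastin. Ddit3 (ENSMUSG00000025408), which encodes the stress transcription factor CHOP, stood at 74.2 ± 5.34 TPM with erastin against 27.2 ± 2.74 TPM in control (SD, n = 3 each). Chac1 (ENSMUSG00000027313), whose enzyme degrades glutathione, stood at 15.9 ± 1.30 against 3.84 ± 1.53 TPM. Cth (ENSMUSG00000028179), an enzyme that makes cysteine from cystathionine, stood at 22.6 ± 2.10 against 8.45 ± 1.22 TPM. Slc7a11 itself (ENSMUSG00000027737) stood at 9.03 ± 1.65 against 5.01 ± 1.19 TPM. Of 35 tested targets of ATF4, the transcription factor of this response, 32 were higher and the median log2 change was 0.51. The list rose against the other genes (camera adjusted p = 5.24e-25), with adjusted p = 0.555 with an estimated correlation. When adjusted over the list alone, 14 members rose, among them Ddit3 by 1.42 ± 0.14 (SE, log2), Chac1 by 1.85 ± 0.24, Cth by 1.32 ± 0.17 and Slc7a11 by 0.74 ± 0.21 (limma adjusted p = 0.00041, 0.000826, 0.000826 and 0.0226). None of them passed when adjusted over all genes tested, where Ddit3 had adjusted p = 0.0618. Relative to the mean of the other controls, the list's median stood at 0.73 in control replicate 1 and between 0.77 and 0.78 with erastin. The median of all genes stood at 0.31 in control replicate 1 and at 0.11, 0.077 and 0.14 in the erastin libraries. List medians given per library here and below are not corrected for that shift. Without control replicate 1 the list had adjusted p = 2.08e-24, or 0.0584 with an estimated correlation, and 32 members rose when adjusted over the list alone.

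Chaperone genes of the endoplasmic reticulum moved in the same direction. Hspa5 (ENSMUSG00000026864), which encodes the chaperone BiP, stood at 864 ± 113 TPM with erastin against 417 ± 24.1 TPM in control. Herpud1, a component of protein degradation at the endoplasmic reticulum, stood at 46.7 ± 1.26 against 21.4 ± 6.25 TPM, and the co-chaperone gene Dnajb9 at 8.71 ± 0.797 against 4.32 ± 0.39 TPM. Of 24 tested genes of the unfolded protein response, 23 were higher, with a median log2 change of 0.40. The list rose (camera adjusted p = 1.58e-18), with adjusted p = 0.555 with an estimated correlation. When adjusted over the list alone, 6 members rose: Hspa5 by 1.04 ± 0.13 (SE), Herpud1 by 1.12 ± 0.20, Dnajb9 by 0.87 ± 0.17, Manf by 0.83, Sdf2l1 by 0.70 and Pdia4 by 0.58. Over all genes none passed, and Hspa5 had limma adjusted p = 0.0822. The list's median stood at 0.42 in control replicate 1 and at 0.54, 0.61 and 0.53 in the erastin libraries. Without control replicate 1 the list had adjusted p = 7.02e-13, or 0.0651 with an estimated correlation, and 18 members rose when adjusted over the list alone.

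Hmox1 and the metallothionein genes were also higher. Hmox1 (ENSMUSG00000005413), the haem-degrading enzyme haem oxygenase 1, stood at 1948 ± 28.1 TPM with erastin against 487 ± 179 TPM in control. The metallothionein genes Mt2 (ENSMUSG00000031762) and Mt1 stood at 3596 ± 354 against 1260.2 ± 254 TPM and at 3079 ± 37.2 against 1474 ± 199.7 TPM. The zinc exporter gene Slc30a1 stood at 6.69 ± 0.413 against 3.19 ± 0.20 TPM. Of 25 tested targets of NRF2, the transcription factor of the oxidant response, 18 were higher with a median of 0.13, and the list rose (camera adjusted p = 5.71e-06, and adjusted p = 0.579 with an estimated correlation). Hmox1 was the 1 member that rose when adjusted over the list alone, by 2.06 ± 0.23 (SE). Gclm, a subunit of the enzyme that starts glutathione synthesis, stood at 124 ± 13.01 against 83.6 ± 17.5 TPM and did not pass there. The NRF2 median stood at 0.51 in control replicate 1 and at 0.32, 0.32 and 0.22 in the erastin libraries. Without control replicate 1 the median change was 0.25 (camera adjusted p = 2.63e-06, and adjusted p = 0.138 with an estimated correlation). The median change of all genes was then 0.11, against 0.0059 with that library, so most of the increase from 0.13 was shared by all genes. Of 6 genes of the metal response, 3 were higher and 3 lower with a median of 0.43. Mt2 rose by 1.53 ± 0.17, Mt1 by 1.07 ± 0.13 and Slc30a1 by 0.88 ± 0.17 when adjusted over the list alone, and the zinc importer gene Slc39a10 fell by 0.81. This list rose (camera adjusted p = 0.00834, and 0.555 with an estimated correlation), and without control replicate 1 its adjusted p was 0.246. Over all genes Hmox1, Mt2 and Mt1 had limma adjusted p = 0.0618, 0.0618 and 0.0777.

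**Figure D1:**
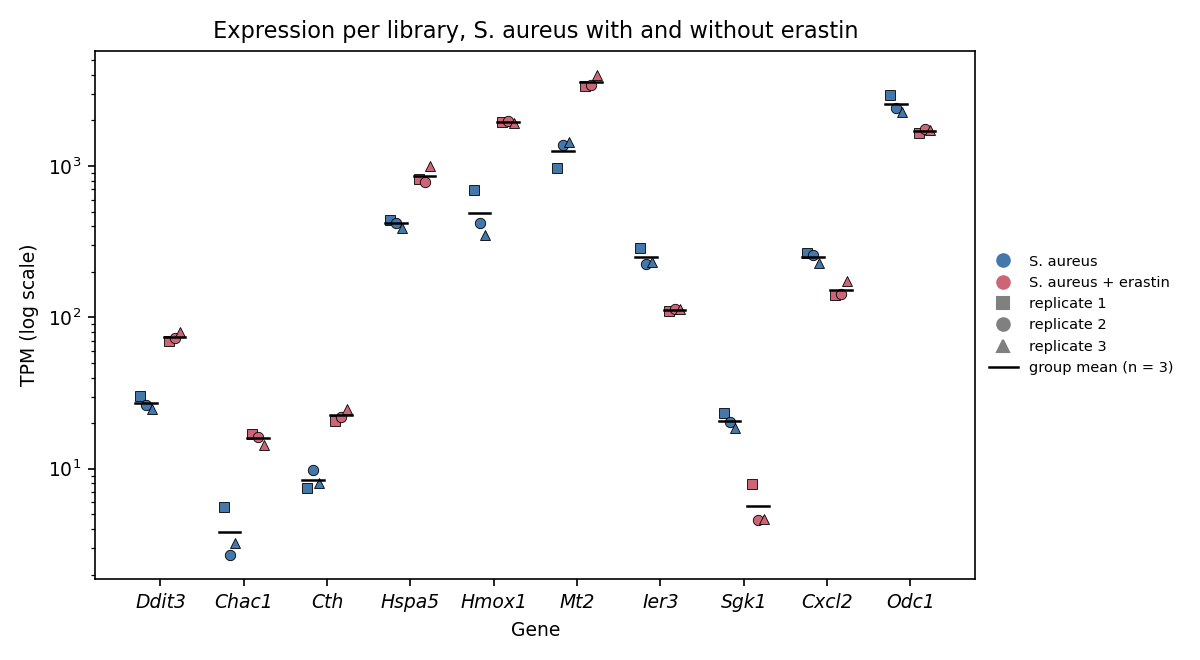
TPM of 10 genes in each of the 6 long RNA libraries, on a log axis, with control and erastin side by side. Squares, circles and triangles are replicates 1, 2 and 3, and each bar is the mean of a group. For Ddit3 the erastin libraries lie between 69.5 and 80.0 TPM, above control replicate 1 at 30.3 TPM and the other controls at 26.4 and 24.98 TPM.

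Interferon-response genes were lower with erastin. Usp18, a brake on interferon signalling, stood at 173 ± 2.85 TPM with erastin against 242 ± 14.7 TPM in control, and Zbp1, a sensor of nucleic acids, at 28.3 ± 1.29 against 40.4 ± 2.56 TPM. Ifit3 stood at 22.0 ± 6.04 against 38.9 ± 5.38 TPM, with the split of reads between it and its near-identical neighbour Ifit3b uncertain. Of 42 tested genes of the type I interferon response, 41 were lower with a median log2 change of -0.38. The list fell (camera adjusted p = 1.57e-17), with adjusted p = 0.555 with an estimated correlation, and 0 members passed limma when adjusted over the list alone (smallest adjusted p = 0.082). The list's median stood at -0.43 and -0.44 in erastin replicates 1 and 2 but at -0.071 in erastin replicate 3. Control replicate 1 stood at -0.057, where the median of all genes was 0.31, against 0.14 in erastin replicate 3.

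Inflammatory genes were lower as well. Ier3 (ENSMUSG00000003541), an early response gene under NF-κB, stood at 112 ± 1.70 TPM with erastin against 249 ± 35.1 TPM in control. Cxcl2, a neutrophil-attracting chemokine, stood at 152 ± 17.8 against 251 ± 19.2 TPM, and Ccl2, which attracts monocytes, at 151 ± 9.89 against 217 ± 37.6 TPM. Of 40 tested NF-κB feedback and early response genes, 34 were lower with a median of -0.33, and the list fell (camera adjusted p = 9.79e-08, and adjusted p = 0.681 with an estimated correlation). Ier3 was the 1 member that fell when adjusted over the list alone, by 1.14 ± 0.14 (SE), and over all genes its limma adjusted p was 0.0777. The immediate early gene Egr2 stood at 0.34 ± 0.199 against 2.26 ± 1.24 TPM. Control replicate 1 stood apart in this list, with a median of 1.01 against 0.052, 0.023 and 0.0031 in the erastin libraries. Without it the NF-κB median was 0.044, above 0, while the median of all genes was 0.11 and the list still ranked lower than other genes (adjusted p = 0.0395, and adjusted p = 0.466 with an estimated correlation). The medians were -0.50 and -0.54 without control replicates 2 and 3. Of 11 chemokine genes 8 were lower with a median of -0.16, and the list fell (camera adjusted p = 0.00104, and 0.555 with an estimated correlation). Cxcl2 fell by 0.72 ± 0.14 when adjusted over the list alone. The chemokine call was lost without control replicate 2 (adjusted p = 0.0525) or control replicate 3 (0.0516), and the median was -0.26 without control replicate 1 (adjusted p = 0.336 with an estimated correlation). Uncorrected for the median of all genes, control replicate 1, with a chemokine median of -0.20, lay among the erastin libraries at -0.33, -0.26 and -0.19. The median of all genes was 0.31 in control replicate 1 and 0.11, 0.077 and 0.14 with erastin. Relative to all genes this control thus lay below every erastin library. Of 13 cytokine genes 9 were lower with a median of -0.29, and the list fell (camera adjusted p = 0.0190, and 0.555 with an estimated correlation), with 0 members past limma when adjusted over the list alone. That call was lost without control replicate 2 (adjusted p = 0.0525) or erastin replicate 1 (0.088, median -0.19). The cytokine median was -0.10 without control replicate 1, where its adjusted p was 0.0103, or 0.336 with an estimated correlation. Its median stood at 0.53 in control replicate 1 and at -0.20, -0.13 and -0.032 in the erastin libraries. Tnf stood at 199.64 ± 12.9 against 322 ± 102 TPM, with control replicate 1 at 438 TPM.

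Genes of sugar metabolism and hypoxia were lower. Hk2, which encodes hexokinase 2 of the opening step of glycolysis, stood at 31.4 ± 2.71 TPM with erastin against 46.5 ± 9.45 TPM in control, and the lactate dehydrogenase gene Ldha at 2473 ± 44.8 against 3068 ± 475 TPM. Control replicate 1 held 3616 TPM of Ldha against 2799 and 2789 TPM in the other controls, and the log2 change was -0.30, or -0.18 without that library. Adm, encoding the peptide adrenomedullin, stood at 4.98 ± 0.857 against 10.9 ± 2.07 TPM, and the adenylate kinase gene Ak4 at 31.4 ± 3.45 against 55.9 ± 9.52 TPM. Of 26 tested glycolysis gene IDs, where Aldoa stands under 2 IDs, 24 were lower with a median of -0.28, and the list fell (camera adjusted p = 5.81e-08, and adjusted p = 0.636 with an estimated correlation), with 0 members past limma when adjusted over the list alone. Of 19 hypoxia genes 14 were lower with a median of -0.22, and the list fell (camera adjusted p = 1.52e-05, and 0.555 with an estimated correlation). Adm and Ak4 fell by 0.99 ± 0.20 and 0.80 ± 0.17 (SE) when adjusted over the list alone (limma adjusted p = 0.0161 for both). In control replicate 1 the glycolysis median stood at 0.62, against -0.042, 0.0034 and -0.13 in the erastin libraries. Without that library the glycolysis median change was -0.065, or -0.17 less that of all genes (adjusted p = 1.82e-04, and adjusted p = 0.336 with an estimated correlation). The hypoxia median stood at -0.25 and -0.20 in erastin replicates 1 and 2 and at -0.020 in erastin replicate 3, and without erastin replicate 3 the change was -0.35.

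**Figure D2:**
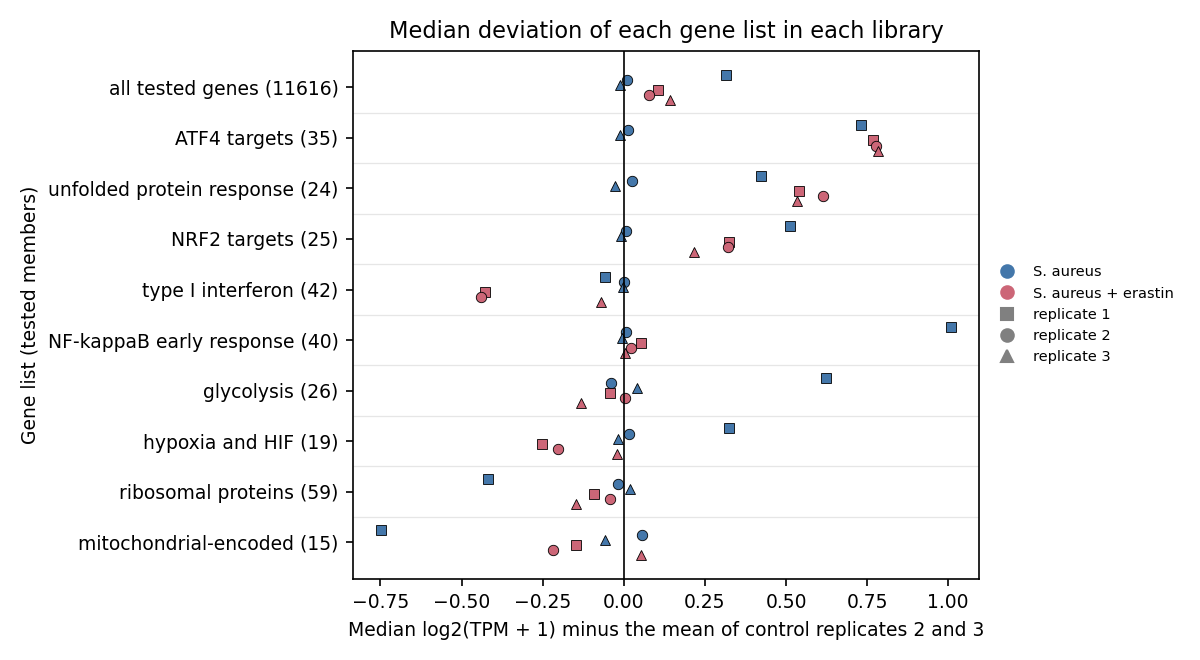
Median log2 deviation of 10 gene lists in each long RNA library from the mean of control replicates 2 and 3. Control replicate 1 stands above 0 for most lists, at 1.01 for the NF-κB list and 0.73 for the ATF4 list, and below 0 for cytosolic ribosomal proteins at -0.42.

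Glutathione and thioredoxin genes were higher for 21 of 32 members with a median of 0.078 (camera adjusted p = 0.0388, and 0.555 with an estimated correlation), and Cth and Chac1 rose when adjusted over the list alone. Genes of the G1/S transition and DNA replication were lower for 31 of 41 (median -0.073), with Cdk2 at -0.34, Ccne1 at -0.31 and Chaf1b at -0.29. Without control replicate 1 these stood at -0.17, -0.13 and -0.073. Ribosome biogenesis and MYC target genes were lower for 28 of 37 (median -0.098), with the polyamine synthesis gene Odc1 at 1714 ± 51.6 against 2548 ± 345 TPM. Camera adjusted p was 0.0388 for the G1/S list and 0.0391 for the MYC list, with adjusted p = 0.817 with an estimated correlation for both. Of 45 members in the list of replication-dependent histones only 4 were tested, so its result does not describe the list as a whole. These 4 were higher (median 0.27, camera adjusted p = 0.0409, and 0.555 with an estimated correlation). They included H1f0, which is known as a replacement linker histone. The histone median stood at 0.42 in control replicate 1, within the range of the erastin libraries at 0.42, 0.54 and 0.36. These values are uncorrected for the median of all genes, which was 0.31 in control replicate 1 and 0.11, 0.077 and 0.14 with erastin. Without control replicate 1, where the median of all genes was 0.11, adjusted p was 0.802 for the glutathione list, 0.488 for G1/S with a median of 0.065, 0.849 for MYC targets with a median of 0.095, and 0.0668 for histones with a median of 0.41. The glutathione call was also lost without erastin replicate 1 (0.0993) or 2 (0.225), and its median was 0.036 without control replicate 3 and 0.042 without erastin replicate 2. The G1/S call was lost without erastin replicate 1 (0.0658), 2 (0.0627) or 3 (0.077), and its median was -0.18 without control replicate 2 and without control replicate 3. The MYC call was lost without erastin replicate 1 (0.051) or 2 (0.117), with medians of -0.19 and -0.17 without control replicates 2 and 3. The histone call was lost without control replicate 2 (0.14), control replicate 3 (0.069) or erastin replicate 1 (0.122).

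Marker genes of other cell types were mostly near 0 TPM. The median marker in the B cell, T and NK cell, neutrophil, erythroid and platelet, stromal, endothelial and epithelial lists stood at or below 0.1 TPM in control. The highest markers were Vim at 1653 TPM in control and 1554 TPM with erastin, Pf4 at 68.2 and 72.4 TPM, and Lcn2 at 59.2 and 64.3 TPM, all genes that macrophages can express. By contrast the macrophage gene Lyz2 stood at 17139.6 ± 1111 TPM in control and 15388 ± 493 TPM with erastin, and Cd68 at 613 ± 179 and 564 ± 31.0 TPM. The endothelial list was the 1 list of other cells with enough tested members, and 4 of 4 were lower with a median of -0.43 (camera adjusted p = 0.0210, and 0.631 with an estimated correlation). Its members Eng, Flt1 and Pecam1 are known in myeloid cells too, and stood at 4.11 ± 0.0808 against 6.86 ± 3.40 TPM, 18.8 ± 0.156 against 24.2 ± 9.36 TPM, and 1.79 ± 0.586 against 2.44 ± 0.596 TPM. The endothelial median stood at 0.93 in control replicate 1, and without that library the log2 changes of Eng, Flt1 and Pecam1 were -0.21, -0.0051 and -0.19. The call was lost without that library (adjusted p = 0.138, median -0.099) or without erastin replicate 2 (0.0658).

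Core ferroptosis and iron genes went both ways. Gpx4, the lipid peroxide-reducing enzyme that restrains ferroptosis, stood at 359 ± 26.1 TPM with erastin against 338 ± 8.79 TPM in control (limma log2 change 0.083, 95% interval -0.19 to 0.35). Acsl4, which supplies the oxidisable lipids, differed by -0.12 ± 0.22 (SE), the transferrin receptor gene Tfrc by -0.26 ± 0.34, and the ferritin gene Fth1 by 0.28 ± 0.15. Without erastin replicate 2 the changes of Gpx4, Acsl4 and Tfrc were 0.046, 0.024 and -0.062, and without erastin replicate 3 they were 0.14, -0.35 and -0.63. Fth1 ranged from 0.16 without control replicate 2 to 0.43 without control replicate 1. Ptgs2, a common marker of ferroptosis, stood at 40.9 ± 11.7 against 69.6 ± 9.67 TPM (adjusted p = 0.788). Of 31 tested ferroptosis genes, 15 were higher and 16 lower (camera adjusted p = 0.558), with a median of -0.0066 and a mean of 0.063. Chac1 was the 1 member that rose when adjusted over the list alone. Of 25 iron and haem genes, 12 were higher and 13 lower (camera adjusted p = 0.26), with a median of -0.075, a mean of 0.092 and a test that pointed up. Hmox1 was the 1 member that rose when adjusted over the list alone, and the haem transporter gene Slc48a1 stood at 89.4 ± 7.07 against 58.5 ± 16.7 TPM. Of the inflammatory genes chosen in advance, Nos2, the inducible nitric oxide synthase, stood at 16.0 ± 1.22 against 32.6 ± 15.5 TPM (adjusted p = 0.982), with control replicate 1 at 50.4 TPM. Il6 stood at 1.31 ± 0.577 against 1.12 ± 0.484 TPM. Il1b, at 0.45 ± 0.0854 against 0.707 ± 0.41 TPM, and the inflammasome adaptor gene Pycard, at 0.02 against 0.0033 TPM, lay under the filter and were not tested.

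The other fixed lists did not pass. Innate immune receptors (adjusted p = 0.157) had a median of 0.011 but a mean of -0.076. The remaining lists that did not pass covered antimicrobial effectors, lysosome, autophagy, cholesterol, fatty acids, lipid efflux, oxidative phosphorylation, mitochondrial genes, voltage-dependent anion channels, heat shock, p53 targets, apoptosis and pyroptosis, mitosis, ribosomal proteins, macrophage identity, alternative activation, antigen presentation and osteoclast genes. Camera adjusted p over the 21 lists that did not pass lay between 0.0675 and 0.831, with 0.453 for the anion channels that erastin is known to bind. In all, 15 of 36 tested lists passed camera, 6 higher and 9 lower. At the same preset correlation, splits of the 6 libraries that mixed the groups gave 3 to 11 lists each. With an estimated correlation 0 lists passed camera (2 at an unadjusted p under 0.05), and 0 passed fry (5 at an unadjusted p under 0.05). Of the 15 lists, 7 passed whichever library was left out: ATF4, NRF2, unfolded protein response, NF-κB, interferon, glycolysis and hypoxia.

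Gene by gene, the lowest p-values were sought among genes with separated groups, a mean of at least 5 TPM and an ordinary symbol. Genes outside this rule could have lower p-values. Among higher genes the lowest p-values under this rule belonged to Ddit3, Hmox1, Mt2, Mt1 and Hspa5. Among lower genes they belonged to Ier3, to Sgk1, a kinase regulated by glucocorticoids and osmotic stress, at 5.72 ± 1.92 against 20.7 ± 2.42 TPM, to Ranbp3l at 5.38 ± 1.99 against 23.8 ± 4.49 TPM, to Chst1, a sulfotransferase gene, at 9.26 ± 1.15 against 37.6 ± 19.1 TPM, and to the retinoic acid receptor gene Rarb at 4.68 ± 0.501 against 10.3 ± 1.08 TPM. None of these passed limma over all 11616 tested genes, where 0 genes had an adjusted p under 0.05 and 506 had an unadjusted p under 0.05 (580.8 expected by chance). Smallest adjusted p was 0.0618, and 1258 genes (10.8%) had groups that did not overlap, where chance gives 10%. Without control replicate 1, 147 genes passed, 123 higher and 24 lower, with adjusted p = 0.00418 for Ddit3, 0.00216 for Hmox1 and 0.00418 for Ier3. Without control replicate 2 the count was 4, without control replicate 3 or erastin replicate 2 it was 1, and without erastin replicate 1 or 3 it was 0.

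Control replicate 1 differed from the other long RNA libraries. Its median absolute log2 difference from the other control libraries was 0.475 and 0.462, against 0.118 between those. Its mean correlation with its own group was 0.955, against 0.969 to 0.979 in the other libraries (across genes, which are not independent replicates). Mitochondrial genes took 2.78% of its TPM, against 3.69% to 5.01% elsewhere, and ribosomal protein genes 12.1% against 14.1% to 15.9%.

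The second comparison asked the same of miRNAs. The shifts were small, and miR-6240 rose most, from 223 ± 112 to 544 ± 102 RPM (SD, n = 3 each), a log2 change of 1.42 (limma adjusted p = 0.0176). Leaving out single libraries gave changes of miR-6240 from 0.93, without control replicate 3, to 1.76. miR-27a-5p rose from 131 ± 8.58 to 159 ± 6.46 RPM, and miR-146a-5p, which is induced by NF-κB signalling, from 40024 ± 743 to 42729 ± 349 RPM. miR-92a-3p, of the miR-17-92 cluster, fell from 3030.4 ± 55.1 to 2674 ± 43.6 RPM. miR-99b-3p fell from 338 ± 7.22 to 281 ± 5.46 RPM and let-7e-5p, from the same genomic cluster, from 6859.8 ± 67.4 to 6172 ± 189 RPM. Of 265 tested miRNAs, 19 passed limma, 9 higher and 10 lower, and 62 had an unadjusted p under 0.05 (13.25 expected by chance). Of the 19, 18 changed by less than 0.3 on the log2 scale. The log2 changes were 0.28 for miR-27a-5p, 0.18 for miR-199a-3p, 0.18 for miR-199b-3p, 0.11 for miR-186-5p, 0.098 for miR-7a-5p and 0.094 for miR-146a-5p (adjusted p from 0.0154 to 0.0426). The mature sequences of miR-199a-3p and miR-199b-3p are identical, so their reads cannot be told apart. On the lower side the changes were -0.26 for miR-99b-3p, -0.23 for let-7c-1-3p, -0.18 for miR-92a-3p, -0.15 for let-7e-5p, -0.14 for miR-99b-5p and -0.14 for miR-674-3p (adjusted p from 0.00367 to 0.0255). With the replicate numbers as a block the limma adjusted p of miR-186-5p was 0.065, and 2 other miRNAs of the 19 lost their call, miR-19b-3p (0.065) and miR-99a-5p (0.0513). With edgeR on the recovered reads and the same block 25 passed, 15 of them among the 19, and adjusted p was 0.0468 for miR-186-5p. There miR-146a-5p (adjusted p = 0.0721), miR-7a-5p (0.11), miR-19b-3p (0.064) and miR-93-5p (0.117) lost their call. Under median-of-ratios scaling 17 passed limma, 5 higher and 12 lower, with 15 of the 19 among them. In that setting miR-186-5p and miR-7a-5p (adjusted p = 0.0572 for both), miR-19b-3p (0.0617) and miR-93-5p (0.106) lost their call. Without the filter 12 passed, with 11 of the 19 among them. The calls of miR-199a-3p (0.0967), miR-199b-3p (0.103), miR-186-5p (0.134), miR-674-3p (0.0627), miR-184-3p (0.0686), miR-19b-3p, miR-93-5p and miR-99a-5p (0.0931 for each) were lost. Among miRNAs chosen in advance, miR-155-5p, miR-21a-5p and miR-223-3p did not pass (adjusted p = 0.54, 0.907 and 0.689).

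Leaving out single libraries changed calls among the 13 miRNAs that passed and were named by the rule fixed in advance. The calls of miR-99b-3p, miR-92a-3p and let-7e-5p held whichever library was left out, and those of the other 10 named miRNAs that passed did not. Without the mean-variance trend these 3 did not pass either (adjusted p = 0.0672, 0.11 and 0.112), and 0 miRNAs passed limma, with 52 at an unadjusted p under 0.05, against 23 that passed edgeR and 27 that passed DESeq2. Without erastin replicate 2 all 10 lost their call (adjusted p from 0.0632 to 0.145), and 5 miRNAs passed. That was the only library whose absence ended the calls of miR-6240 (0.0684) and miR-99b-5p (0.0632). Without erastin replicate 1, 9 miRNAs passed, and miR-146a-5p, miR-186-5p, miR-199a-3p, miR-199b-3p, miR-674-3p, miR-27a-5p and miR-7a-5p lost their call (0.0533 to 0.0791). Without erastin replicate 3, 11 passed, and let-7c-1-3p, miR-146a-5p, miR-186-5p, miR-199a-3p and miR-199b-3p lost it (0.0693 to 0.191). Without control replicate 1, 12 passed, and let-7c-1-3p, miR-186-5p, miR-199a-3p, miR-199b-3p and miR-7a-5p lost it (0.0733 to 0.106). Without control replicate 2, 16 passed, and miR-186-5p (0.0854) and miR-674-3p (0.0541) lost it. Without control replicate 3, 18 passed, and let-7c-1-3p (0.0624), miR-186-5p (0.108) and miR-27a-5p (0.0528) lost it.

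**Figure D3:**
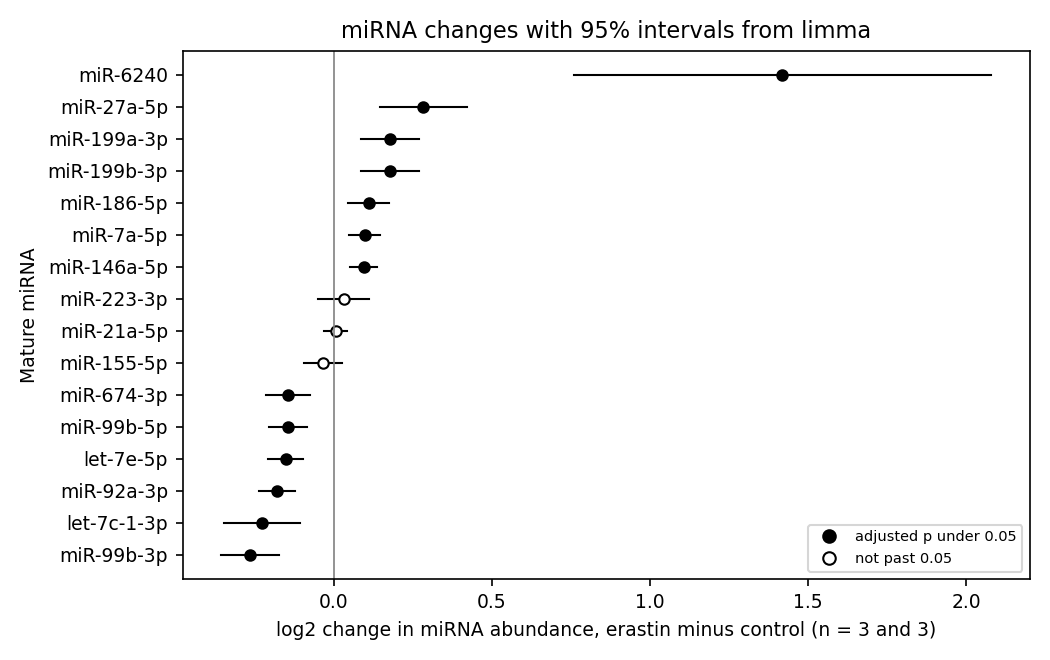
Log2 change (erastin minus control, log2(RPM + 1) scale) of 16 named miRNAs, with 95% limma intervals as bars. Filled points have an adjusted p under 0.05. miR-6240 lies at 1.42, and the other points lie between -0.26 and 0.28.

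The let-7 family, known for restraining growth genes, was lower as a group. Of 9 tested members 8 were lower with a median of -0.063, and the list fell (camera adjusted p = 1.53e-04, and adjusted p = 0.142 with an estimated correlation). When adjusted over the list alone 5 fell: let-7e-5p by 0.15, let-7b-5p by 0.12, let-7c-5p by 0.12, let-7d-5p by 0.076 and let-7a-5p by 0.063. Adjusted over the list alone, let-7a-5p did not pass without erastin replicate 1 (0.07), and let-7d-5p did not without control replicate 1 (0.0747) or 2 (0.094) or erastin replicate 1 (0.0974) or 3 (0.0544). Under quantile normalization only let-7e-5p of these 5 passed over the list (limma adjusted p = 0.00928), with let-7b-5p at 0 and let-7d-5p at 0.018. Without the trend let-7a-5p and let-7d-5p did not pass there (0.12 for both). The list kept its call whichever library was left out (adjusted p 3.17e-05 to 0.00229), and under quantile normalization its adjusted p was 0.98. In the miR-17-92 list and its paralogues (camera adjusted p = 0.894), miR-17-5p, miR-19b-3p and miR-93-5p rose and miR-92a-3p and miR-106b-3p fell when adjusted over the list alone. There miR-17-5p and miR-106b-3p did not pass without control replicate 1 (0.0544 for both) or erastin replicate 3 (0.0727 for both), nor did miR-19b-3p without erastin replicate 3 (0.0578). In the inflammation-responsive list (0.188) 2 members rose and 4 fell when adjusted over the list alone, and in the p53-induced list (0.188) 2 rose, miR-34a-5p and miR-192-5p. With the replicate block miR-210-3p, 1 of the inflammation-responsive members that rose, did not pass over its list (0.0643). It did not pass either, for instance, without control replicate 1 (0.0531) or 3 (0.113). Of the 4 that fell, miR-125a-5p and miR-125b-5p did not pass without control replicate 2 (0.0755 and 0.0675) or erastin replicate 1 (0.101 for both). With single libraries left out, miR-34a-5p kept its pass over the p53-induced list in 1 of 6 cases (without control replicate 1), and miR-192-5p in 2 (also without erastin replicate 3). The myeloid list (0.696) had a median of 0.021 but a mean of -0.033, and miR-146a-5p was the 1 member that rose when adjusted over the list alone. Of 6 miRNAs of other tissues, 3 were higher and 3 lower (0.696).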

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

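Library weights, the robust prior, the estimated correlation without control replicate 1, DESeq2 and edgeR with the block were chosen after seeing the data. Of 85 named results, 80 took the opposite sign under no alternative: 49 of 53 genes, 15 of 16 miRNAs and 16 of 16 lists by their test. Over single results and settings, 1136 values kept their side of the threshold without a change of sign, 86 newly passed, 102 no longer passed and 10 changed sign. The cause was not tested unless stated.

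The long RNA count of 0 (limma, 506 at unadjusted p under 0.05) was 7 with median-of-ratios scaling, 9 with quantile normalization, 2628 with library weights (2094 higher, 534 lower, control replicate 1 weighted 0.059), and 0 to 147 when single libraries were left out. With the replicate number as a block it was 49. Same-numbered long RNA libraries deviated together at 0.109, -0.182 and 0.091, and not every sample correlated best with its own number, so these numbers were not taken as pairs. The median of all genes moved from 0.0059 to 0.11 without control replicate 1 and to 0.10 with weights. Less that shift, the ATF4 and unfolded protein response medians without control replicate 1 were 0.65 and 0.44.

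The 15 gene lists became 0 with an estimated correlation (camera), 0 with fry and 0 with an estimated correlation without control replicate 1 (4 at unadjusted p under 0.05), and 10 to 18 with single libraries left out. With library weights 14 lists passed camera, of which 9 were among the 15. The NF-κB list was among those that no longer passed with weights (adjusted p = 0.0695). Quantile normalization ended the calls of the G1/S (0.12) and MYC lists (0.19), and a filter at 5 TPM, with fewer genes tested, those of the metal response (0.0862, median -0.014), G1/S (0.0636) and MYC lists (0.0641). With no filter, where more members near 0 TPM were tested, the glutathione (0.174) and endothelial calls (0.0955) were lost, and the cytokine, chemokine, metal response and endothelial medians were -0.035, -0.077, 0.17 and -0.069, and without the trend those of the G1/S (0.0527), MYC (0.0584) and histone lists (0.058). A pseudocount of 0.1 TPM ended the histone call (0.052). Rescaling without the most abundant genes gave medians of 0.25 for NRF2 and -0.32 for chemokines.

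The 19 miRNAs became 1 with a minimum log2 change of 1, 12 without the filter, where more were tested, 12 with quantile normalization, of which 6 were shared, and 0 without the trend (limma, 52 at unadjusted p under 0.05, against 23 with edgeR and 27 with DESeq2). Leaving out single libraries gave 5 to 18. With the pairing as a block 20 passed, 16 of them shared, while miR-186-5p (adjusted p = 0.065), miR-19b-3p (0.065) and miR-99a-5p (0.0513) lost their call and no miRNA list changed its call. With edgeR and the block, miR-146a-5p (adjusted p = 0.0721), miR-7a-5p (0.11), miR-19b-3p (0.064) and miR-93-5p (0.117) did not pass. With edgeR alone miR-7a-5p (0.0569) and miR-93-5p (0.083) did not. The let-7 call was lost with an estimated correlation (0 lists) and with quantile normalization (0 lists, median 0, since abundant miRNAs keep their rank and so get the same value), and 2 lists passed without the filter. Quantile normalization gave 0, and so no direction, for miR-146a-5p, miR-7a-5p, miR-21a-5p, miR-223-3p, let-7b-5p, miR-93-5p and miR-125b-5p for the same reason. It also ended the calls of miR-99b-5p (-0.018, adjusted p = 0.591), miR-674-3p (0.312), miR-6240 (0.266), miR-186-5p (0.204), let-7c-1-3p (0.0805) and miR-27a-5p (0.0646).

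Signs changed for 5 of the 85 named results. Outside these, miR-99a-5p and let-7d-5p fell by 0.11 and 0.076 but stood at 0.014 and 0.018 with quantile normalization. Il6 ranged from -0.078 to 0.27 with single libraries left out and was -0.15 with weights. Acsl4 ranged from -0.35 to 0.024 with single libraries left out. With weights, which give control replicate 1 little part, Chaf1b was 0.011 and Flt1 0.0075, against -0.29 for each with equal weights. miR-21a-5p was -0.0058 with median-of-ratios scaling, -0.0063 with edgeR, -0.0062 with edgeR and the block, and -0.0059 to 0.013 with single libraries left out. The unknown depth of the long RNA libraries leaves the error of low genes such as Il6, Egr2 and Pycard unmeasured.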

Other observations

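The fits, scalings and left-out libraries below and the counts over other splits of the samples were planned, and the tests that weigh explanations (position, correlation, the ribosomal protein list and the bounds on list medians) were chosen or revised after the values were seen. Bootstrap intervals below resampled genes and not libraries, so they do not measure the spread between samples. Further members of the ATF4 list are named here after their values were seen. Trib3, a pseudokinase that feeds back on ATF4, stood at 35.9 ± 2.32 TPM with erastin against 9.30 ± 4.20 TPM in control. The serine synthesis gene Psph stood at 170.01 ± 18.3 against 88.7 ± 6.79 TPM, the asparagine synthetase gene Asns at 156 ± 8.99 against 89.2 ± 6.56 TPM, and Atf4 itself at 504 ± 20.2 against 259 ± 52.8 TPM. All 4 rose when adjusted over the ATF4 list alone (limma adjusted p = 0.00104, 0.00125, 0.00155 and 0.00162). Psat1, another serine synthesis gene, differed by 0.052 and the glutamine carrier gene Slc38a2 by -0.066. In the p53 list, which did not pass as a group, the growth arrest gene Gadd45a rose by 1.07 and Btg2 fell by 0.93 when adjusted over the list alone (0.028 and 0.0492).

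Among miRNAs, clusters were looked at after their values were seen and were not tested as groups. From the genomic cluster of miR-99b, let-7e and miR-125a, miR-99b-5p, miR-99b-3p and let-7e-5p fell, while the others did not pass. miR-125a-5p stood at 6825 ± 183 RPM with erastin against 7292 ± 271 RPM in control (log2 change -0.095, limma adjusted p = 0.08), miR-125a-3p at 29.7 ± 2.80 against 36.1 ± 1.59 RPM (0.12), and let-7e-3p at 8.68 ± 1.89 against 11.7 ± 1.13 RPM (0.179). From the related cluster of miR-99a, let-7c-1 and miR-125b-2, miR-99a-5p fell by 0.11 (adjusted p = 0.0358), let-7c-5p by 0.12 (0.00367) and let-7c-1-3p by 0.23 (0.0255). The call of miR-99a-5p was lost with the replicate block (0.0513) and whichever single library was left out except erastin replicate 1 (0.0639 to 0.183). It was also lost without the filter (0.0931) and without the trend (0.181). With quantile normalization its change was 0.014, above 0 (limma adjusted p = 0.591). miR-99a-3p at -0.15 (0.305), miR-125b-5p at -0.061 (0.0878) and miR-125b-2-3p at -0.11 (0.0978) did not pass. In the miR-17-92 cluster members differed in direction. miR-92a-3p fell by 0.18, miR-19b-3p rose by 0.084 (0.0426), and miR-20a-5p differed by 0.0036 (0.972). The call of miR-19b-3p was lost with the replicate block (0.065), with median-of-ratios scaling (0.0617), and without control replicate 2 (0.0854) or 3 (0.0965) or erastin replicate 1 (0.0831), 2 (0.171) or 3 (0.146).

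Control replicate 1 stood apart from the other long RNA libraries. Its highest correlations were 0.963 and 0.960, with erastin replicates 2 and 1. Those with control replicates 3 and 2 were 0.957 and 0.953, and that with erastin replicate 3 was 0.948. All lay below the lowest of 0.976 among the other 5. This argues against a wrong label or admixed erastin RNA as the whole difference, but not against either as a part of it. Over the 147 genes called without it, its median position between the other controls at 0 and erastin at 1 was 0.74 (bootstrap interval 0.62 to 0.90), but 0.44 (0.31 to 0.63) once the median of all genes was subtracted, and over the 24 falling genes it was 0.21 (-0.21 to 0.58), or 0.56 (0.16 to 1.02) after that subtraction, so a wrong label or partial admixture cannot be told apart from other differences by position. A lower yield of short transcripts stays open. The ribosomal protein list stood at -0.42 (-0.53 to -0.31), close to the 5th percentile of random lists of like size and expression. That percentile was -0.42 and their median -0.31, and 3.84% of them were as low. These lists were drawn from genes that include the ribosomal protein genes themselves, so the comparison cannot decide. Mitochondrial-encoded genes stood at -0.75 (-1.01 to -0.62), below all 10000 random lists matched to them. No biological explanation was tested, as the design names no difference between the controls.

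The ATF4 and unfolded protein response lists were higher with erastin. Under 3 other scalings the lowest median of both lists was 0.40, so the rise did not depend on the choice among these. They moved the median change of all genes little, from 0.0059 to values between 0.0029 and 0.0195. They could therefore not decide whether scaling is a cause. Control replicate 1 stood above the other controls in both lists, at 0.73 and 0.42 against 0.31 for all genes. Less the median of all genes, the changes were 0.51 and 0.39 with it. Without it they were 0.65 and 0.44 (0.29 to 0.64 for the lower). Leaving it out was thus bound to widen the difference and gives no separate support. A response to erastin is a candidate explanation, and a batch difference between the groups stays open, since the labels give no batches.

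The NF-κB and glycolysis lists were lower with erastin while control replicate 1 was high in both. Without that library the glycolysis median, less that of all genes, was -0.17 (-0.26 to -0.095). The camera call was kept at the preset correlation (adjusted p = 0.336 with an estimated correlation). The list thus stayed lower without control replicate 1. The interval resampled genes that move together (estimated correlation 0.73), so that library as the whole cause cannot be excluded by it. For the NF-κB list the median less that of all genes was -0.063 (-0.21 to 0.0017). There control replicate 1 and a difference between the groups cannot be told apart. The interval reaches 0 while the camera call was kept at the preset correlation (adjusted p = 0.466 with an estimated correlation). An effect of erastin on both lists stays open and untested beyond these values.

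The 6 libraries of each table can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 long RNA genes, as few as any, so that 10 of 10 splits gave as many, and the highest other gave 3. It gave 15 gene lists against 3 to 11 in the other splits, and 1 split gave as many. Camera at the preset correlation thus also called lists in every split that mixed the groups. The real split gave 19 miRNAs against 1 in the highest other, and 1 split gave as many. It gave 1 miRNA list against 1, and 2 splits gave as many. Among the miRNA splits that part all 3 pairs of numbers, the 3 others gave 0 miRNAs (limma, at most 9 at an unadjusted p under 0.05) and 0 lists. Setting control replicate 1 with erastin replicates 1 and 2 gave 1853 long RNA genes at an unadjusted p under 0.05 against 506 in the real split, which points to a structure of the samples other than the groups.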
